A study of Mus musculus with 20 samples.

How the data were processed

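RNA was measured in ovaries of 20 female mice of the Ames dwarf stock, 5 mice in each of 4 groups: normal (N/df) and dwarf (df/df), at 6 and 22 months. Per the labels' protocols, ovaries were flash frozen, RNA was extracted with Trizol, and Illumina libraries were made from polyadenylated RNA. Per the submitters' processing notes, Bowtie2, TopHat, TopHat2 2.0.10, HTSeq, DESeq and edgeR were used with the mm10 genome; the role of each tool, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited files hold counts of reads per gene, 1 file per library, with 23457 genes and 5 summary rows in the format of HTSeq.

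The summary rows held 9.84 to 17.6% of each file's counts, and the row for reads outside genes was 0 in each file. They were left out of library sizes and tests. The values are whole numbers and were treated as raw counts. No columns of per-sample values were left unused (0). Groups were taken from the labels, which give the genotype and age of each library, and each library was taken as 1 mouse. Totals over genes ranged from 1365640 to 36068284, with group medians of 13733504 and 14479403 in normal mice at 6 and 22 months and 16846616 and 10120399 in dwarf mice. Rn45s took 6.18 ± 4.88, 6.76 ± 2.61, 5.62 ± 1.61 and 6.35 ± 2.22% of the counts (mean ± SD, same order).

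Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 16099, and libraries were scaled by TMM. A model of the 4 group means over all 20 libraries was fitted with robust dispersion and quasi-likelihood estimates in edgeR (common dispersion 0.165). Contrasts were 22 against 6 months in normal and in dwarf mice, dwarf against normal at 6 and at 22 months, and the difference of the age responses. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. Counts described as adjusted over the list alone use the p-values of a list's own genes. Overlaps of calls are given with the number expected for independent lists.

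There were 23 gene lists and 12 marker sets, 35 in all, written from general knowledge before the data were examined. The 34 with at least 5 tested members went through camera with a preset correlation of 0.01, camera with a correlation estimated per list, and fry. The red blood cell set had 2 tested members of the 10 listed and was not tested. A list's score in a library is the mean log2 CPM of its genes (prior count 2).

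Genes named in the text follow a rule set in advance. It takes a panel (Prlr, Ghr, Igf1, Fshr, Lhcgr, Amh, Foxo3, Cdkn2a), the 5 largest rises and 5 largest falls of each pairwise comparison among called genes with a mean of at least 2 CPM in the higher group and groups that do not overlap, up to 3 called members with the smallest p of each list, and the 10 smallest p of the interaction. Some genes that the rule names are not reported here. Ovgp1 and Rn45s are named as markers of single libraries, and genes named for the fit without the libraries in doubt were chosen after their values were seen. Coordinates, and overlaps of exons between genes, were taken from the gene annotation deposited with the series.

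The test was run on simulated data with the same depths and dispersions, 16099 genes each, of which 100 changed 2-fold and 100 changed 4-fold. It recovered 43% and 79% of these for age in normal mice, 38% and 83% for age in dwarf mice, 37% and 77% for genotype at 6 months, 35% and 71% for genotype at 22 months and 16% and 60% for the interaction. False calls were 3, 2, 8, 4 and 2. The simulated genes were drawn independently from a single mean profile, so no library stood apart from its group and genes did not correlate. Only genes above a minimum mean level were changed. These numbers therefore do not give the recovery or the false calls to be had in the real libraries.

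The contrasts, thresholds, lists and a first set of alternatives were fixed before the data were examined. Those alternatives were RLE and upper quartile scaling, no low-count filter or at least 1 CPM in 5 libraries, DESeq2, limma voom with quality weights, non-robust estimates, only the groups compared, the replicate number as a block, each library left out in turn, the 3 libraries with title numbers 21 to 23 left out, and a further 2-fold threshold. For lists they were the estimated correlation and fry, and for overlaps an adjusted p under 0.01. With 1 library left out, a comparison was tested only if that library belonged to its own groups. Others were chosen after seeing the data: leaving out 3 libraries in doubt, the oviduct score as a covariate, dwarf 22-month replicates 1 and 4 summed as 1 library, and Rn45s and Lars2 removed. Reads were not used here, and neither alignment nor sex, strain or variant checks on reads were made.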

Results

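Ovarian messenger RNA was sequenced from 20 female mice of the Ames dwarf stock, in a full cross of 2 genotypes and 2 ages. Dwarf mice (df/df) lack growth hormone, prolactin and thyrotropin. Heterozygous mice (N/df) have a normal pituitary and are called normal here. Each of the 4 groups (normal and dwarf, at 6 and 22 months) held 5 mice with 1 library each. The series title names reproductive ageing in these long-lived mice as its subject. Counts assigned to genes ranged from 1365640 to 22429386 per library in normal mice at 6 months and from 5186090 to 20266823 at 22 months. In dwarf mice they ranged from 14224520 to 36068284 at 6 months and from 5399377 to 13448164 at 22 months. Levels below are mean CPM (counts scaled by library size) ± SD over the 5 libraries of a group. Fold changes are log2 values from edgeR. The SE after ± is not an edgeR estimate but was derived as the absolute log2 fold change over the square root of the test's F statistic. Adjusted p-values are Benjamini-Hochberg values from edgeR's quasi-likelihood test for single genes and from camera for gene lists. Of 23457 genes in the files, 16099 had enough counts to be tested. Largest rises and falls are taken among called genes with at least 2 CPM in the higher group and no overlap between the groups.

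Some libraries stood apart from their group. In normal 6-month replicate 2, the oviduct secretory gene Ovgp1 reached 4775 CPM against 9.73 to 60.0 in the other 4 libraries, and the luteal list scored a mean log2 CPM of 3.95 against 8.52 to 8.98. Normal 6-month replicate 3 was the shallowest library, with 1365640 counts and 14.8% of them in the ribosomal RNA gene Rn45s. In normal 22-month replicate 3, the B and plasma cell list scored 6.38 against 1.61 to 2.31 in the other 4 libraries of that group. Dwarf 22-month replicates 1 and 4 were closer to each other (chi-square per degree of freedom 2.51 over 13528 genes) than any of the other library pairs within a group (13.2 or more, 40 pairs in all), but differed by more than sampling noise and were counted as 2 samples.

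The first comparison asked how normal ovaries changed between 6 and 22 months. Oocyte genes fell together. Rfpl4, an oocyte-specific gene, went from 9.37 ± 6.10 to 0.234 ± 0.268 CPM (SD, n = 5; log2 -5.05 ± 0.869, edgeR adjusted p = 0.00787). Ooep, part of the maternal complex of the egg cortex (mm10 chromosome 9, 78376903 to 78378588), fell from 16.3 ± 8.58 to 2.13 ± 1.18 CPM (log2 -2.92 ± 0.480, edgeR adjusted p = 0.00745). Amh, the hormone that granulosa cells of growing follicles secrete (chromosome 10, 80805248 to 80807648), fell from 175 ± 112 to 7.17 ± 5.10 CPM (log2 -4.65 ± 0.715, edgeR adjusted p = 0.00671). Genes of macrophages and lymphocytes rose, among them Ctss, a lysosomal protease of antigen-presenting cells, from 27.6 ± 10.9 to 152 ± 125 CPM (log2 2.51 ± 0.418, edgeR adjusted p = 0.00745).

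Of 33 oocyte genes tested in normal mice, 31 fell with age (33 adjusted over the list alone), with a mean log2 change of -3.90 ± 0.694 (SD over genes; camera adjusted p = 1.06e-34, or adjusted p = 0.151 with an estimated correlation). Of 34 proliferation genes, 17 fell and none rose (27 adjusted over the list alone; mean log2 change -1.24 ± 0.565, camera adjusted p = 2.75e-17, or adjusted p = 0.323 with an estimated correlation). Among them were the mitotic kinase Aurka at log2 -1.93 ± 0.319 (edgeR adjusted p = 0.00745) and the spindle checkpoint kinase Bub1b at -2.25 ± 0.454 (edgeR adjusted p = 0.0103). Of 20 granulosa genes, 4 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.000172, or adjusted p = 0.504 with an estimated correlation). The vesicular transporter gene Slc18a2 fell by 3.65 ± 0.780 on the log2 scale. The same mice differed in oviduct markers, whose list score was 4.13 ± 2.6 at 6 months (1.47 to 8.06, the highest value being replicate 2) and 7.30 ± 0.95 at 22 months (6.25 to 8.85). Of 10 oviduct markers 1 rose (camera adjusted p = 0.000123), none of 11 ciliated cell genes passed alone (camera adjusted p = 4.24e-05), and 1 of 9 surface epithelium genes rose (camera adjusted p = 8.16e-05). These 3 lists gave adjusted p = 0.401, 0.419 and 0.323 with an estimated correlation. Without the 3 libraries in doubt named below, 10 of 10 oviduct, 11 of 11 ciliated cell and 7 of 9 surface epithelium genes rose (mean log2 change 5.31, 4.48 and 2.74, against 1.60, 1.14 and 1.20 with all libraries). Without normal 22-month replicate 2 alone, the oviduct mean was lower, at 0.849 (camera adjusted p = 0.00197). With the oviduct score as a covariate, the oocyte list still averaged a log2 change of -2.55, with 0 of its genes past edgeR's adjusted threshold.

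Immune lists moved the other way in normal ovaries. With age, 14 of 27 macrophage genes rose (24 adjusted over the list alone; mean log2 change 1.76 ± 1.14, camera adjusted p = 6.39e-16, or adjusted p = 0.151 with an estimated correlation). The lysozyme gene Lyz2 rose by log2 2.04 ± 0.356 (85.5 ± 34.7 to 346 ± 218 CPM), although its reads may be shared with its near-identical neighbour Lyz1. Rises also counted 13 of 19 T and NK cell genes (19 adjusted over the list alone, camera adjusted p = 9.41e-11), 10 of 15 B and plasma cell genes (15, camera adjusted p = 9.87e-08). Also higher were 6 of 10 MHC class II genes (10, camera adjusted p = 6.45e-06) and 6 of 27 chemokine and cytokine genes (13, camera adjusted p = 7.8e-06). Each of these lists gave adjusted p = 0.323 with an estimated correlation, as did the interferon (2 of 26 genes, 13 adjusted over the list alone, camera adjusted p = 1.32e-08) and complement lists (2 of 20, 7 adjusted over the list alone, camera adjusted p = 4.71e-05). Without normal 22-month replicate 3 the mean log2 change was 1.58 for T and NK cell, 1.83 for B and plasma cell, 1.63 for MHC class II and 1.08 for chemokine genes (2.67, 4.12, 2.84 and 1.94 over all libraries). The T cell kinase gene Zap70 rose by log2 1.78 ± 0.378 and Cxcl13, a chemokine that draws B cells into follicles, by 6.51 ± 1.42 (0.727 ± 0.773 to 79.7 ± 160 CPM, edgeR adjusted p = 0.0133). Normal 22-month replicate 3 held the highest level of Cxcl13 (366 CPM), and without it the log2 change was 3.23 for Cxcl13 (edgeR adjusted p = 0.0432), 3.27 for the B cell kinase gene Blk and 1.92 for Ctss. B cell genes were among the largest rises of genes whose groups did not overlap, which leaves out Cxcl13, and of these Blk (log2 5.54 ± 0.996, edgeR adjusted p = 0.00812) passed in every fit with a library left out. Faim3, Pou2af1 and Ms4a1 (log2 5.52, 5.56 and 5.47) did not pass without normal 22-month replicate 3. In that fit their log2 changes were 3.18, 3.05 and 1.77 (edgeR adjusted p = 0.12, 0.146 and 0.296). They also missed without normal 6-month replicates 1, 4 or 5 (edgeR adjusted p = 0.0538 to 0.0703). Without normal 6-month replicate 2, Faim3 and Pou2af1 had larger log2 changes (6.61 and 8.14). Of 6 mast cell genes 4 rose (4 adjusted over the list alone, camera adjusted p = 3.52e-05, or adjusted p = 0.145 with an estimated correlation).

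The largest falls among genes whose groups did not overlap were in Ccno, a cyclin of multiciliated cells and oocytes (log2 -3.09 ± 0.404, edgeR adjusted p = 0.00348), Ninj2, Asb4, Sct and Tmem255b. The fall of Sct, which encodes secretin, was lost without normal 6-month replicate 4 (edgeR adjusted p = 0.056). Foxo1, a transcription factor of granulosa cells, fell from 357 ± 165 to 122 ± 22.1 CPM (log2 -1.55 ± 0.289, edgeR adjusted p = 0.00814). Igf1 had a log2 change of -1.01 ± 0.301 (70.1 ± 21.8 to 34.9 ± 15.8 CPM, edgeR adjusted p = 0.0489). That call ended without any one of normal 22-month replicates 1 to 4 (edgeR adjusted p = 0.0825, 0.106, 0.116 and 0.0671) or normal 6-month replicates 3, 4 and 5 (0.0573, 0.0507 and 0.079). The cell cycle inhibitor gene Cdkn2a stood at 2.00 ± 1.13 and 6.00 ± 2.06 CPM (log2 1.58 ± 0.487, edgeR adjusted p = 0.0568). Fshr, the follicle-stimulating hormone receptor gene, stood at 18.3 ± 16.0 and 3.23 ± 3.39 CPM (log2 -2.54 ± 0.823, edgeR adjusted p = 0.0702). Prlr, Ghr, Lhcgr and Foxo3 had edgeR adjusted p of 0.544, 0.841, 0.780 and 0.614.

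In all, edgeR called 1086 genes with age in normal mice, 419 higher (38.6%) and 667 lower. This balance turned in other fits, to 62.7% higher without normal 6-month replicate 2, 54.4% with limma voom and 2741 higher against 2107 lower without the 3 libraries in doubt. Without normal 6-month replicate 2 the count was 4384, without normal 6-month replicate 4 it was 530 and without normal 22-month replicate 3 it was 481. Without title numbers 21 to 23 (normal 6-month replicate 5, normal 22-month replicate 3 and dwarf 22-month replicate 5) it was 188, 16.5% of them higher. Fitted on the 10 normal libraries alone edgeR called 0 genes and with the oviduct covariate 1, while over all 20 libraries 3748 had an unadjusted p under 0.05 and DESeq2 and limma voom called 1766 and 3859. Without the 3 libraries in doubt (normal 6-month replicates 2 and 3 and normal 22-month replicate 3, an alternative chosen after seeing the data) 4848 genes were called, 947 of them among the 1086. The oocyte, proliferation and mast cell lists, which had not passed with an estimated correlation over all libraries, then had adjusted p = 0.0228, 0.031 and 0.0488 with it, while the mean log2 change was 1.65 for T and NK cell genes (2.67 over all libraries) and 2.43 for B and plasma cell genes (4.12). Normal 6-month replicate 2 was lowest of its group in the oocyte and proliferation scores (-1.51 and 2.54) and highest in the mast cell score (3.71). Leaving it out enlarges the age change of each of these lists, so their passing gives no separate support.

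**Figure D1:**
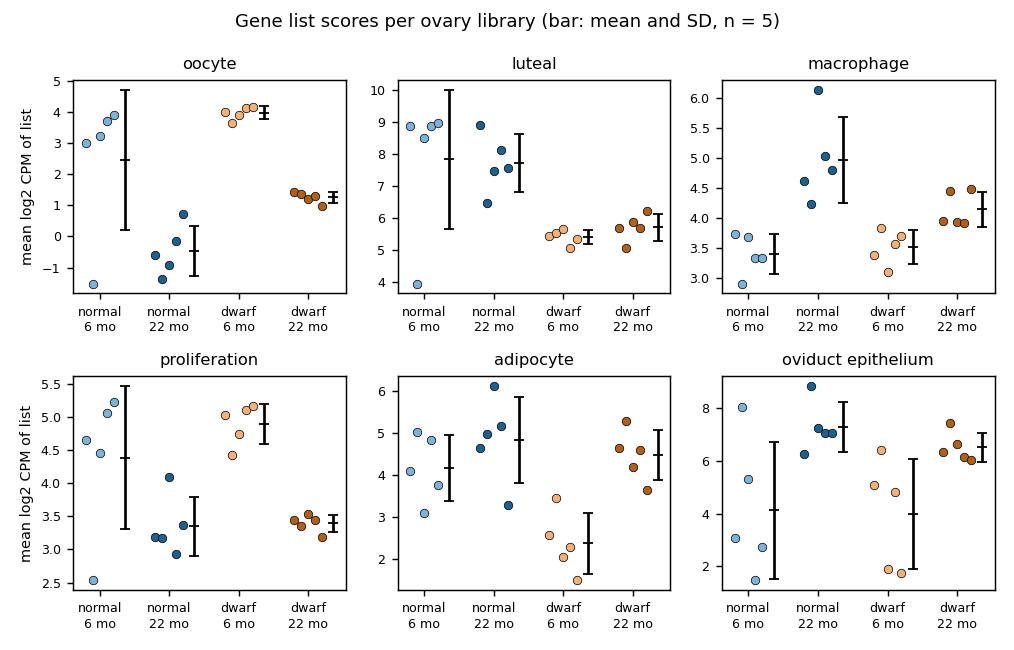
Scores of 6 gene lists (mean log2 CPM over the list's genes, vertical axes) in each of the 20 libraries, by group on the horizontal axes, with bars at the mean and SD of 5 libraries. The oocyte list averaged 2.46 and -0.46 in normal mice and 3.97 and 1.26 in dwarf mice at 6 and 22 months, with normal 6-month replicate 2 lowest of its group at -1.51.

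The second comparison followed the same ages in dwarf ovaries. Oocyte genes fell here too, led by the germ cell transcription factor gene Sohlh2, from 2.34 ± 0.536 to 0.0691 ± 0.110 CPM (SD, n = 5; log2 -5.05 ± 0.843, edgeR adjusted p = 0.00168, and log2 -6.17 without dwarf 22-month replicate 1). Sohlh1 (chromosome 2, 25842997 to 25847248) fell from 5.36 ± 1.01 to 0.212 ± 0.210 CPM (log2 -4.76 ± 0.780, edgeR adjusted p = 0.00148). Amh fell from 390 ± 92.8 to 47.9 ± 7.96 CPM (log2 -3.02 ± 0.652, edgeR adjusted p = 0.0078). Genes of dividing cells fell, such as Ube2c, a ubiquitin enzyme of mitosis, from 51.0 ± 9.62 to 10.2 ± 0.962 CPM (log2 -2.32 ± 0.372, edgeR adjusted p = 0.0014). Fat cell genes rose, among them Fabp4, a fatty acid carrier, from 6.87 ± 4.55 to 52.8 ± 27.6 CPM (log2 2.94 ± 0.656, edgeR adjusted p = 0.0092).

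Of the 33 oocyte genes, 28 fell in dwarf mice (33 adjusted over the list alone; mean log2 change -2.80 ± 0.684, camera adjusted p = 9.03e-22, or adjusted p = 0.427 with an estimated correlation). Proliferation genes fell in 25 of 34 cases (29 adjusted over the list alone; mean log2 change -1.52 ± 0.568, camera adjusted p = 9.03e-22, or adjusted p = 0.427 with an estimated correlation). Aurka went from 29.4 ± 7.90 to 6.38 ± 1.09 CPM (log2 -2.20 ± 0.319, edgeR adjusted p = 0.000758). Oviduct markers moved with age in dwarf mice as well. None of 10 passed alone, and the list score was 3.99 ± 2.08 at 6 months and 6.52 ± 0.55 at 22 months (camera adjusted p = 0.00336, or adjusted p = 0.771 with an estimated correlation). None of 11 ciliated cell genes passed alone either (camera adjusted p = 0.00189, or adjusted p = 0.771 with an estimated correlation). Ovgp1 itself lay between 1376 and 2620 CPM in the dwarf 22-month libraries and at 435, 914, 11.9, 490 and 21.2 CPM in dwarf 6-month replicates 1 to 5. With the oviduct score as a covariate, the oocyte list averaged a log2 change of -2.03 with 5 genes still lower. Granulosa genes gave camera adjusted p = 0.0931, with 0 higher and 2 lower of 20, and luteal genes 0.448, with none of 11 past the threshold.

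Adipocyte genes rose in 8 of 11 cases in dwarf ovaries (9 adjusted over the list alone; mean log2 change 2.12 ± 1.20, camera adjusted p = 8.34e-07, or adjusted p = 0.427 with an estimated correlation). The fat hormone gene Adipoq rose from 1.83 ± 1.79 to 17.3 ± 7.76 CPM (log2 3.26 ± 0.814, edgeR adjusted p = 0.0163, and log2 4.04 without dwarf 6-month replicate 2) and Lpl by log2 0.86 ± 0.208. Surface epithelium genes rose in 2 of 9 cases (4 adjusted over the list alone, camera adjusted p = 0.000177, or adjusted p = 0.555 with an estimated correlation), with the uroplakin gene Upk1b at log2 1.76 ± 0.40. Of the 27 macrophage genes 2 rose (0 adjusted over the list alone, camera adjusted p = 0.00374, or adjusted p = 0.771 with an estimated correlation). Interferon genes rose in 2 of 26 cases (1 adjusted over the list alone; mean log2 change 0.82, or 0.295 without dwarf 22-month replicate 2 and 1.43 without dwarf 6-month replicate 4, camera adjusted p = 0.000193). Of 20 complement genes 1 rose (1 adjusted over the list alone; mean log2 change 0.63, or 0.409 without dwarf 22-month replicate 2, camera adjusted p = 0.0216, or 0.0614 without dwarf 22-month replicate 5). Both lists had adjusted p = 0.771 with an estimated correlation. No mast cell gene passed (2 of 6 higher adjusted over the list alone, camera adjusted p = 0.0494, or adjusted p = 0.555 with an estimated correlation). That list call ended without dwarf 22-month replicates 1, 2 or 5 or dwarf 6-month replicates 1, 4 or 5 (camera adjusted p = 0.0519 to 0.0935). None of the T and NK, B and plasma or MHC class II genes passed (camera adjusted p = 0.163, 0.119 and 0.462). Matrix genes went both ways, with 3 higher and 6 lower of 33 (3 and 7 adjusted over the list alone, camera adjusted p = 0.166). Ctgf, a matricellular growth factor gene (chromosome 10, 24595442 to 24598682), fell from 558 ± 132 to 112 ± 17.7 CPM (log2 -2.32 ± 0.295, edgeR adjusted p = 0.00039). The basement membrane collagen Col4a2 fell by 1.37 ± 0.285 on the log2 scale, and the proteoglycan lumican gene Lum rose from 12.0 ± 5.46 to 60.6 ± 8.73 CPM (log2 2.33 ± 0.365, edgeR adjusted p = 0.00118).

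The largest rises in dwarf mice were in the serine protease gene Prss29 (0.842 ± 0.918 to 19.4 ± 6.68 CPM, log2 4.56 ± 1.14, edgeR adjusted p = 0.016, and log2 5.27 without dwarf 6-month replicate 4), 5830411N06Rik, Acsm3 (log2 4.14 ± 0.471, edgeR adjusted p = 0.000255; its locus overlaps Eri2, so the assignment of reads is uncertain), Klk1b27 and the cartilage matrix gene Comp (log2 3.64 ± 0.891, edgeR adjusted p = 0.0148). The call of Klk1b27, one of many similar kallikrein genes, was lost in each of the 10 fits with a library left out (edgeR adjusted p = 0.0532 without dwarf 22-month replicate 2 up to 0.114 without dwarf 6-month replicate 5). Among the largest falls were also Kcns2, the piRNA pathway gene Mael and Mafa (log2 -4.47, -4.36 and -4.24, with -6.09 for Kcns2 without dwarf 22-month replicate 4). Foxo1 fell from 532 ± 135 to 202 ± 23.5 CPM (log2 -1.40 ± 0.287, edgeR adjusted p = 0.0059). Of 25 DNA repair genes 3 fell (camera adjusted p = 0.226). The other genes of the panel fixed in advance did not pass. Igf1, Prlr, Ghr, Fshr, Lhcgr, Foxo3 and Cdkn2a had edgeR adjusted p of 0.672, 0.790, 0.986, 0.403, 0.942, 0.542 and 0.135.

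edgeR called 1802 genes with age in dwarf mice, 470 higher (26.1%) and 1332 lower. The share of higher genes was 47.4% with limma voom, 45.7% with the dwarf libraries alone and 46.5% without the 3 libraries in doubt. Leaving out dwarf 22-month replicates 1, 2, 3 or 4 gave 1079, 954, 1127 and 1069 genes, and leaving out dwarf 6-month replicates 1, 3, 4 or 5 gave 1014, 972, 1185 and 802. The dwarf libraries alone gave 5169 genes, DESeq2 2747, limma voom 7519 and the oviduct covariate 642, while counting dwarf 22-month replicates 1 and 4 as 1 library gave 1107. In limma voom these replicates had the highest quality weights of all libraries (3.89 and 3.93), so its count leans on a pair that may be 1 mouse. Without the 3 normal libraries in doubt the count was 4697, all of the 1802 among them. The oocyte and proliferation lists each then had adjusted p = 0.0446 with an estimated correlation.

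**Figure D2:**
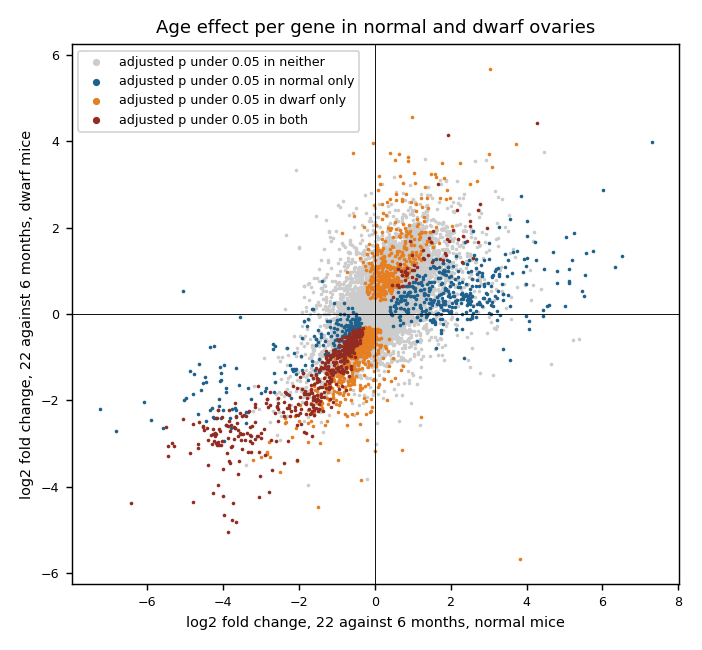
Log2 fold change between 6 and 22 months of each tested gene in normal mice (horizontal axis) and dwarf mice (vertical axis), coloured by whether edgeR's adjusted p was under 0.05 in neither, one or both genotypes. Genes called in both genotypes, 59 higher and 464 lower, lie in the upper right and lower left only.

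The age responses of the genotypes came from different mice and overlapped. Called in both were 59 genes that rose and 464 that fell, against 12.2 and 55.2 for independent lists of the same sizes, and 0 genes were called in opposite directions. Across the 16099 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.653 and Spearman's rho = 0.651. Of 2365 genes called in either genotype, 2211 (93.5%) had the same sign in both. Oviduct scores also rose with age in both genotypes (4.13 to 7.30 in normal and 3.99 to 6.52 in dwarf mice). With that score as a covariate, edgeR called 1 gene with age in normal and 642 in dwarf mice. The overlap therefore cannot tell a shared age response of the ovary from a shared change in oviduct content. Amh, Aurka, Foxo1, Hsd11b2 and Ooep were among the genes that fell in each genotype, with Hsd11b2, which inactivates glucocorticoids, at log2 -1.68 ± 0.354 in normal and -1.74 ± 0.353 in dwarf mice.

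The third comparison set dwarf against normal ovaries at 6 months. Sult1e1 and Hsd17b3, neither of them in the steroidogenesis list, were far higher in dwarf mice. Sult1e1, the estrogen sulfotransferase gene (chromosome 5, 87575968 to 87591611), stood at 0.220 ± 0.381 CPM in normal and 10.9 ± 5.18 in dwarf ovaries (SD, n = 5; log2 6.91 ± 0.793, edgeR adjusted p = 0.000173). Hsd17b3, whose product makes testosterone (chromosome 13, 64058274 to 64089201), stood at 0.944 ± 1.48 and 29.5 ± 17.1 CPM (log2 6.18 ± 0.775, edgeR adjusted p = 0.000237). Genes of the corpus luteum were far lower, with Akr1c18, which inactivates progesterone (chromosome 13, 4132627 to 4150631), at 164 ± 143 and 0.999 ± 0.424 CPM (log2 -7.29 ± 1.30, edgeR adjusted p = 0.00345). Sfrp4, a secreted Wnt inhibitor (chromosome 13, 19623175 to 19632823), stood at 1003 ± 594 and 10.6 ± 7.70 CPM (log2 -6.57 ± 0.921, edgeR adjusted p = 0.000656).

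Of 11 luteal genes, 5 were lower in dwarf mice and none higher (10 adjusted over the list alone; mean log2 difference -3.11 ± 2.45, camera adjusted p = 2.62e-09, or adjusted p = 0.265 with an estimated correlation). They included the prostaglandin F receptor gene Ptgfr (log2 -5.94 ± 0.947, edgeR adjusted p = 0.0016). Cyp11a1, the enzyme that opens steroid synthesis (chromosome 9, 58015017 to 58027023), stood at 2582 ± 1523 and 167 ± 98.9 CPM (log2 -3.95 ± 0.833, edgeR adjusted p = 0.0097). Steroidogenesis genes were lower in 4 of 24 cases (8 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0214) and cholesterol supply genes in 4 of 29 (5 adjusted over the list alone, camera adjusted p = 3e-05), each with adjusted p = 0.703 with an estimated correlation. The steroidogenesis call was lost without dwarf 6-month replicate 2 or normal 6-month replicates 1, 3, 4 or 5 (camera adjusted p = 0.0899 to 0.12). Its mean log2 difference was -0.907 to -1.01 in these fits and -1.04 over all libraries. Without the 3 libraries in doubt, 7 steroidogenesis genes were lower and 2 higher (camera adjusted p = 1.45e-05), and 16 of 29 cholesterol supply genes were lower (3.04e-13). With an estimated correlation these gave adjusted p = 0.159 and 0.198. Normal 6-month replicate 2, left out there, was lowest of its group in both scores. The sterol reductase gene Dhcr7 had a log2 difference of -2.46 ± 0.450 and the mitochondrial electron carrier gene Fdx1 of -3.50 ± 0.594. Markers of fat moved with these lists, with 3 of 11 adipocyte genes lower in dwarf mice (9 adjusted over the list alone; scores 4.16 ± 0.79 and 2.37 ± 0.72, camera adjusted p = 4.02e-08, or adjusted p = 0.239 with an estimated correlation). No smooth muscle gene passed the threshold alone (4 of 10 lower adjusted over the list alone; scores 8.07 ± 1.14 and 7.22 ± 0.54, camera adjusted p = 0.00284, or adjusted p = 0.703 with an estimated correlation). The smooth muscle call was lost without normal 6-month replicate 2 (camera adjusted p = 0.17) and without the 3 libraries in doubt (mean log2 difference -1.15, then -0.05, camera adjusted p = 0.79). Normal 6-month replicate 2, low in luteal markers, lay with the dwarf libraries for several of these genes, at 1.75 CPM for Akr1c18.

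Dwarf ovaries at 6 months also had more Insl3, a peptide hormone of theca cells (chromosome 8, 71689252 to 71690577), at 67.9 ± 27.2 against 1.15 ± 1.36 CPM (log2 6.68 ± 0.788, edgeR adjusted p = 0.000237). Its locus overlaps Jak3 and the strand setting of the counting is not given in the sources used here, so this assignment is uncertain. Insl3 was the 1 theca gene of 12 that passed (camera adjusted p = 0.00051, or adjusted p = 0.53 with an estimated correlation, and by camera 0.106 without normal 6-month replicate 2 and 0.115 without the 3 libraries in doubt). Of 5 tested Sertoli cell markers, 3 were higher in dwarf mice (3 adjusted over the list alone, camera adjusted p = 4.83e-07, or adjusted p = 0.00348 with an estimated correlation). These were the prostaglandin D synthase gene Ptgds (chromosome 2, 25466712 to 25469749), at 95.6 ± 137 and 4459 ± 1891 CPM (log2 5.61 ± 0.764, edgeR adjusted p = 0.000524), Aard (log2 2.75 ± 0.415) and the tight junction gene Cldn11 (log2 2.15 ± 0.354). Normal 6-month replicate 3 held 341 CPM of Ptgds against 30.9 to 36.5 in the rest of its group, and without it the log2 difference of Ptgds was 7.02. Cyp21a1, a steroid hydroxylase best known from the adrenal cortex, was higher by log2 5.43 ± 0.839, with uncertainty from its neighbouring pseudogene. The complement gene C7 rose from 4.41 ± 4.24 in normal to 87.1 ± 41.8 CPM in dwarf mice (log2 4.70 ± 0.580, edgeR adjusted p = 0.000237). Kit, a growth factor receptor of oocytes, mast cells and other lineages, was higher by log2 2.12 ± 0.318, and Ctgf by 2.67 ± 0.300.

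Cish, a feedback inhibitor switched on by prolactin and growth hormone receptors, was lower in dwarf mice, at 8.18 ± 1.62 against 65.7 ± 35.6 CPM (log2 -3.00 ± 0.494, edgeR adjusted p = 0.00183). In the growth hormone, IGF and insulin list 2 genes were higher and 3 lower of 24 (2 and 4 adjusted over the list alone, camera adjusted p = 0.867). Thra, a thyroid hormone receptor gene, was higher by log2 0.72 ± 0.147 and Pik3r1 by 0.97 ± 0.183. Antioxidant genes split, 2 higher and 4 lower of 28 (6 and 13 adjusted over the list alone, camera adjusted p = 0.0197, 0.145 without dwarf 6-month replicate 4, 0.32 without normal 6-month replicate 3, 0.389 without the 3 libraries in doubt, or adjusted p = 0.703 with an estimated correlation). The glutathione transferase gene Gsta3, of a family of similar genes, stood at log2 2.47 ± 0.391 and the haem oxygenase gene Hmox1 at -2.0 ± 0.420. Wnt10b, a Wnt ligand, had the largest fall (60.0 ± 53.1 to 0.346 ± 0.133 CPM, log2 -7.40 ± 0.977, edgeR adjusted p = 0.000392). The somatostatin receptor gene Sstr1 had a log2 difference of -5.02 ± 0.963 (-4.28 without normal 6-month replicate 5). No oocyte gene passed alone (mean log2 difference 0.76 ± 0.524, camera adjusted p = 4.83e-07, or adjusted p = 0.703 with an estimated correlation). The mean was 0.41 with 2 genes higher without the 3 libraries in doubt, which include normal 6-month replicate 2 with few oocyte transcripts (camera adjusted p = 0.0292). Of the panel, Amh, Fshr, Lhcgr, Prlr, Ghr, Igf1, Foxo3 and Cdkn2a had edgeR adjusted p of 0.336, 0.770, 0.0764, 0.222, 0.149, 0.354, 0.290 and 0.142.

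Lists that leaned higher in dwarf mice with few calls or none were T and NK cell (0 of 19 genes), MHC class II (0 of 10), granulosa (1 of 20) and proliferation genes (0 of 34), with camera adjusted p of 0.0161, 0.0429, 0.0179 and 0.0179 and adjusted p = 0.861 with an estimated correlation. Each of the 4 was lost without normal 6-month replicate 2 (camera adjusted p = 0.245, 0.119, 0.842 and 0.842) and without dwarf 6-month replicate 4 (0.145, 0.446, 0.0522 and 0.0619). Without normal 6-month replicate 2 the mean log2 differences were 0.724, 1.5, -0.137 and 0.0232 in this order (0.828, 1.2, 0.112 and 0.237 over all libraries). Without the 3 libraries in doubt, T and NK cell and MHC class II genes passed (0.842 and 1.75, camera adjusted p = 0.0209 each, or adjusted p = 0.835 with an estimated correlation). Granulosa and proliferation genes did not (camera adjusted p = 0.61 and 0.351). Of the 10 fits with a library left out, 7, 6, 2 and 3 lost these calls.

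In all, edgeR called 735 genes between genotypes at 6 months, 365 higher and 370 lower in dwarf mice, and 61.1% were higher without normal 6-month replicate 2. Leaving out dwarf 6-month replicates 1 or 5 gave 380 and 369 genes, leaving out normal 6-month replicate 2 gave 1459, and the 10 libraries of that age alone gave 244. DESeq2 called 1414, limma voom 1860 and the fit with the oviduct covariate 1164. Without the 3 libraries in doubt the count was 1991, 624 of them among the 735. The luteal and Sertoli lists then had adjusted p = 0.0281 and 0.0191 with an estimated correlation. Normal 6-month replicate 2, left out there, had the lowest luteal score of its group (3.95), so the passing of the luteal list gives no separate support. Markers of the oviduct also moved in that fit, with 2 of 10 oviduct and 1 of 11 ciliated cell genes higher in dwarf mice (mean log2 difference 2.32 and 2.68, camera adjusted p = 0.0292 and 0.0136, or adjusted p = 0.835 with an estimated correlation). Over all libraries none of either list passed (-1.29 and -0.47, camera adjusted p = 0.66 and 0.759).

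**Figure D3:**
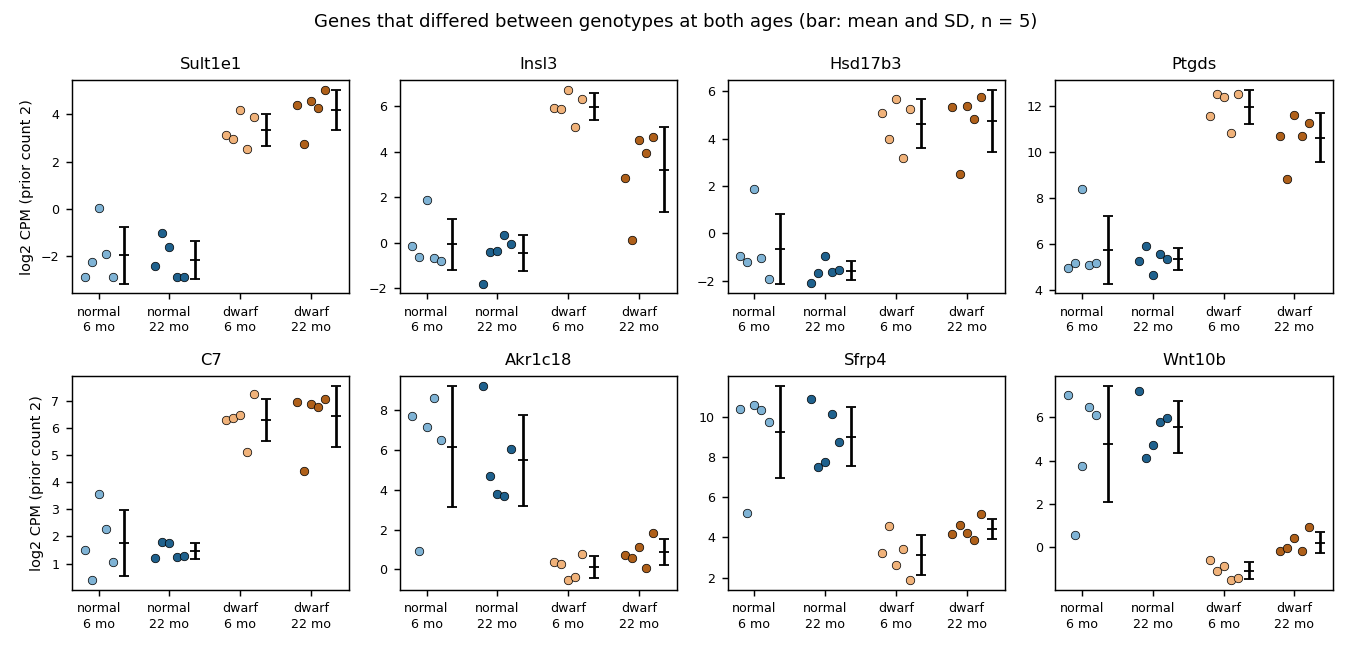
Level of 8 genes in each library (log2 CPM with a prior count of 2, vertical axes) by group on the horizontal axes, with bars at the mean and SD of 5 libraries. Sult1e1, Insl3, Hsd17b3, Ptgds and C7 were higher in dwarf mice at both ages, and Akr1c18, Sfrp4 and Wnt10b were lower.

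The fourth comparison set dwarf against normal ovaries at 22 months. Sult1e1 and Hsd17b3 led again, at 0.119 ± 0.154 and 20.5 ± 9.26 CPM (SD, n = 5; log2 7.30 ± 0.731, edgeR adjusted p = 2.68e-05, and log2 8.04 without normal 22-month replicate 2) and at 0.209 ± 0.102 and 34.1 ± 18.3 CPM (log2 7.28 ± 0.779, edgeR adjusted p = 6.32e-05). C7 (chromosome 15, 4988762 to 5063773) stood at 2.65 ± 0.580 in normal and 102 ± 45.7 CPM in dwarf ovaries (log2 5.25 ± 0.572, edgeR adjusted p = 6.32e-05). Old dwarf ovaries had fewer transcripts of mast cell proteases, with Cma1 at 26.7 ± 11.8 in normal and 2.90 ± 1.5 CPM in dwarf mice (log2 -3.22 ± 0.564, edgeR adjusted p = 0.00351). The stimulus-induced transcription factor gene Egr2 stood at 8.79 ± 1.81 and 2.16 ± 0.800 CPM (log2 -2.01 ± 0.350, edgeR adjusted p = 0.00343).

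Immediate-early genes were lower in 5 of 13 cases in old dwarf mice (6 adjusted over the list alone; mean log2 difference -1.05 ± 0.594, camera adjusted p = 4.24e-08, or adjusted p = 0.0175 with an estimated correlation). Among them was Junb at log2 -1.35 ± 0.281 (edgeR adjusted p = 0.0113). Sertoli markers were higher in 2 of 5 cases (3 adjusted over the list alone, camera adjusted p = 8.92e-06, or adjusted p = 0.0175 with an estimated correlation), with Ptgds at 42.4 ± 12.8 and 1884 ± 1005 CPM. Of 11 luteal genes 4 were lower (6 adjusted over the list alone; mean log2 difference -2.28 ± 2.12, camera adjusted p = 5.9e-06, or adjusted p = 0.34 with an estimated correlation). They were led by Sfrp4 at log2 -5.12 ± 0.861 (edgeR adjusted p = 0.00264) and Akr1c18 at -6.32 ± 1.27 (edgeR adjusted p = 0.0097), whose normal libraries ranged from 12.7 to 589 CPM. Without normal 22-month replicate 1 the log2 difference was -4.04 for Akr1c18 and -4.46 for Sfrp4. Theca genes were higher in 2 of 12 cases (2 adjusted over the list alone, camera adjusted p = 7.28e-05, or adjusted p = 0.34 with an estimated correlation). These were Insl3 at log2 4.52 ± 0.707 and the hedgehog target gene Gli1 at 1.32 ± 0.289, both of which overlap another gene (Jak3 and Arhgap9).

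Oocyte genes as a list were higher in old dwarf than in old normal ovaries, with 2 of 33 past the threshold over all genes and 18 adjusted over the list alone (mean log2 difference 1.86 ± 0.860, camera adjusted p = 2.31e-16, or adjusted p = 0.34 with an estimated correlation). Granulosa genes were higher in 2 of 20 cases (2 adjusted over the list alone, camera adjusted p = 4.85e-06, or adjusted p = 0.47 with an estimated correlation). The nuclear receptor gene Nr0b1 was higher by log2 2.02 ± 0.422 and Amh by 2.78 ± 0.664 (7.17 ± 5.10 against 47.9 ± 7.96 CPM, edgeR adjusted p = 0.0239). The Amh call ended without normal 22-month replicates 1, 2 or 3 (edgeR adjusted p = 0.0608, 0.054 and 0.0552) or dwarf 22-month replicate 4 (0.055). Macrophage genes were lower in 4 of 27 cases and higher in 1 (16 and 1 adjusted over the list alone; mean log2 difference -1.12 ± 0.851, camera adjusted p = 7.01e-07, or adjusted p = 0.352 with an estimated correlation). That mean was -0.56 without the 3 libraries in doubt (camera adjusted p = 0.00181). Of B and plasma cell genes 1 of 15 was lower (13 adjusted over the list alone, camera adjusted p = 0.00152, or adjusted p = 0.762 with an estimated correlation). That call was lost without the 3 libraries in doubt, which include normal 22-month replicate 3 with the most of their transcripts (mean log2 difference -2.45, then -0.08, camera adjusted p = 0.611). Normal 22-month replicate 3 alone ended it (camera adjusted p = 0.47), as it did the calls of T and NK cell (0 of 19 genes, camera adjusted p = 0.00335, then 0.514), MHC class II (0 of 10, 0.0441, then 0.678) and chemokine genes (1 of 27 lower, 0.00173, then 0.17). The MHC class II call was lost in 6 of 10 such fits. Interferon genes leaned lower with none of 26 called (mean log2 difference -0.62, -1.12 without dwarf 22-month replicate 2 and -0.389 without normal 22-month replicate 2, camera adjusted p = 0.00128), as did smooth muscle genes with none of 10 (-0.67, camera adjusted p = 0.0376, lost in 5 of 10 such fits, up to 0.248 without normal 22-month replicate 4). These 5 lists had adjusted p = 0.771, 0.806, 0.47, 0.766 and 0.806 with an estimated correlation. Mast cell genes were lower in 3 of 6 cases and higher in 1, Kit (4 and 1 adjusted over the list alone, camera adjusted p = 0.0087, or adjusted p = 0.34 with an estimated correlation). Kit stood at 53.2 ± 31.3 and 275 ± 91.7 CPM (log2 2.37 ± 0.319, edgeR adjusted p = 0.000448).

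Igf1 was higher in old dwarf ovaries, at 89.0 ± 33.0 against 34.9 ± 15.8 CPM (log2 1.35 ± 0.302, edgeR adjusted p = 0.0168), as were Igf2 (log2 1.64 ± 0.211, a locus that overlaps Igf2as), the quinone reductase gene Nqo1 (1.86 ± 0.249) and Gsta3 (2.42 ± 0.381). Cish (log2 -2.26 ± 0.485, or -1.48 without normal 22-month replicate 4) and Hmox1 (-2.06 ± 0.419) were lower. Cdkn2a, a cell cycle inhibitor gene that accumulates in senescent cells, stood at 1.75 ± 1.12 against 6.00 ± 2.06 CPM (log2 -1.76 ± 0.480, edgeR adjusted p = 0.0451). Its call was lost without dwarf 22-month replicates 1, 2, 4 or 5 (edgeR adjusted p = 0.0781, 0.0975, 0.135 and 0.129) or normal 22-month replicates 1 to 4 (0.0883, 0.0544, 0.11 and 0.076). The other largest rises were Cyp21a1 (log2 5.51 ± 0.793), Cbln4 (0.0304 CPM in normal and 3.86 ± 2.10 in dwarf ovaries, edgeR adjusted p = 0.000553) and the ammonium transporter gene Rhcg (0.0262 and 2.38 ± 2.18 CPM, edgeR adjusted p = 0.00569). The other largest falls were Ces2a (-6.39 ± 1.30, -5.41 without normal 22-month replicate 4 and -7.41 without dwarf 22-month replicate 4), the neuropeptide gene Adcyap1 (-6.34 ± 0.996), Cldn18 (-6.29 ± 1.38, -4.69 without normal 22-month replicate 4, lost without dwarf 22-month replicate 4 at edgeR adjusted p = 0.0533) and Wnt10b (-5.88 ± 0.916, or -5.24 without normal 22-month replicate 1). Prlr, Ghr, Fshr, Lhcgr and Foxo3 had edgeR adjusted p of 0.774, 0.232, 0.17, 0.125 and 0.970.

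edgeR called 614 genes between genotypes at 22 months, 315 higher (51.3%) and 299 lower in dwarf mice, and with upper quartile scaling 65.1% of the calls were higher. That share was 69.6% and 71.4% without dwarf 22-month replicates 1 and 4, and 43.1% with limma voom. Leaving out dwarf 22-month replicates 1, 3, 4 or 5 gave 263, 376, 262 and 321 genes and leaving out normal 22-month replicate 1 gave 399, while counting dwarf replicates 1 and 4 as 1 library gave 272 and leaving out title numbers 21 to 23 gave 323. DESeq2 called 1201, limma voom 2291 and the fit with the oviduct covariate 931. The limma voom count again leans on dwarf 22-month replicates 1 and 4, which had its highest quality weights. Without the 3 libraries in doubt the count was 1762, 589 of them among the 614. The Sertoli list then had adjusted p = 0.0303, and the immediate-early list adjusted p = 0.0619, with an estimated correlation.

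The genotype differences at the 2 ages, again from different mice, shared 148 genes higher and 106 lower in dwarf ovaries, against 7.14 and 6.87 for independent lists, and 0 genes were called in opposite directions. Across genes the log2 differences correlated with Pearson's r = 0.513 and Spearman's rho = 0.42. Of 1095 genes called at either age, 1008 (92.1%) had the same sign at both. Sult1e1, Hsd17b3, Insl3, Cyp21a1, Ptgds, C7, Kit, Gsta3 and Nqo1 were higher at both ages, and Akr1c18, Sfrp4, Wnt10b, Cish and Hmox1 lower.

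The last comparison asked whether the age response differed between the genotypes. No single gene passed. The smallest p belonged to Tk2, a mitochondrial thymidine kinase gene (log2 difference of the age responses -0.74 ± 0.151, edgeR adjusted p = 0.533). Next were the angiotensin-converting enzyme gene Ace (-2.02 ± 0.431), Cyr61 (-2.08 ± 0.446), Phyhip (1.71 ± 0.374), Tsku, Spn, Ctgf (-1.72 ± 0.403), Lum (2.11 ± 0.498), Pik3ip1 and Epha5, all with an edgeR adjusted p of 0.533. Ctgf stood at 88.1, 57.9, 558 and 112 CPM in normal mice at 6 and 22 months and dwarf mice at 6 and 22 months, and Lum at 47.7, 55.7, 12.0 and 60.6 CPM. The panel's adjusted p ranged from 0.769 for Igf1 to 0.993 for Ghr and Lhcgr.

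edgeR thus called 0 of 16099 genes for the interaction, with 1127 at an unadjusted p under 0.05, while DESeq2 called 17 and limma voom 9. In simulated data with the same library depths, 16% of genes with a 2-fold and 60% with a 4-fold interaction were recovered. Those data had no outlying library and no correlated genes, so recovery in the real libraries may differ. Of 34 lists 15 passed camera's preset correlation and 0 the estimated one. The age response of 5 immune lists was lower in dwarf than in normal mice, with a mean log2 difference of -1.61 for chemokine (camera adjusted p = 5.37e-05), -1.13 for macrophage (camera adjusted p = 4.03e-08), -2.32 for T and NK cell (1.58e-09), -3.29 for B and plasma cell (1.61e-07) and -2.52 for MHC class II genes (3.19e-06). Each of these lists had adjusted p = 0.46 with an estimated correlation. Their means without the 3 libraries in doubt were -1.02, -0.68, -1.22, -1.61 and -1.8 (camera adjusted p = 0.0287, 0.0062, 0.00324, 0.0018 and 0.00462), and -0.72, -0.59, -1.2, -0.98 and -1.27 without normal 22-month replicate 3 alone. The interferon and complement lists did not pass (-0.46 and -0.28, camera adjusted p = 0.211 and 0.216, or 0.277 and 0.341 without the 3 libraries in doubt). That of adipocyte genes was higher by 1.5 (camera adjusted p = 1.61e-07, or adjusted p = 0.329 with an estimated correlation). That of oocyte genes was higher by 1.10 (camera adjusted p = 5.31e-05, or adjusted p = 0.736 with an estimated correlation), and that of immediate-early genes was lower, at -0.86 (camera adjusted p = 3.24e-07, or adjusted p = 0.0825 with an estimated correlation). Without the 3 libraries in doubt edgeR called 202 genes, 117 higher and 85 lower, and the age response of oviduct and ciliated cell markers was lower in dwarf mice (mean log2 difference -3.57 and -2.93, camera adjusted p = 0.000589 and 0.000893, or adjusted p = 0.504 and 0.505 with an estimated correlation).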

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

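The tests of tissue dilution, of other tissue, of a mislabelled library and of repeated samples were chosen only after the result was seen; the thinning test of the oocyte list and the splits were planned. The depth of normal 6-month replicate 2 was also tested after the result was seen. Single libraries were compared with the rest of their group by the gap to the nearest library over the group's range, where 0.71 or more happens by chance in about 1 in 20 groups of 5. Of 8 groups of library measures 2 passed (0.4 by chance), of 140 groups of list scores 20 (7 by chance) and of 524 groups of named genes 60 (26.2 by chance), and the genes are not independent.

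Normal 6-month replicate 2 had more of these than any other library. It was lowest of its group in the list scores of oocyte (0.835), granulosa (0.712), luteal (0.909), theca (0.878), steroidogenesis (0.939) and proliferation genes (0.716) and highest in interferon (0.763) and surface epithelium genes (0.847). It was also lowest in Prlr (0.884), Lhcgr (0.782), Amh (0.855), Asb4 (0.81), Ooep (0.8), Dppa3 (0.723), Rfpl4 (0.827), Aurka (0.769), Plk1 (0.891), Bub1b (0.778), Sohlh1 (0.845), Sohlh2 (0.734), Cdc20 (0.817), Ube2c (0.76), Akr1c18 (0.727), Sfrp4 (0.843), Fdx1 (0.848), Cyp11a1 (0.926), Dhcr7 (0.716), Fdps (0.786), Scarb1 (0.87) and Cldn11 (0.865).

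Dwarf 22-month replicate 2 was high in MHC class II (0.923), interferon (0.935) and immediate-early scores (0.765) and in Cldn4 (0.827) and Plin4 (0.798). It was low in steroidogenesis (0.843) and cholesterol supply scores (0.784) and in Prlr (0.733), Lhcgr (0.843), Prss29 (0.856), Mafa (0.779), Hsd17b3 (0.724), Cyp21a1 (0.931), Cyp11a1 (0.873), C7 (0.894), Gsta3 (0.847), Nqo1 (0.828) and Cbln4 (0.845). Dwarf 22-month replicate 5 was low in the Rn45s share (0.878) and Ghr (0.817) and high in the matrix score (0.799), Gli1 (0.796) and Col15a1 (0.788).

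Normal 6-month replicate 3 was high in the Rn45s share (0.873), oxidative phosphorylation (0.856) and antioxidant scores (0.867), Insl3 (0.758), Hsd17b3 (0.742) and Ptgds (0.931), and low in Il7r (0.732), 5830411N06Rik (0.738) and Lpl (0.782). Normal 22-month replicate 3 was high in B and plasma cell (0.852) and chemokine scores (0.757), Pou2af1 (0.715), Ms4a1 (0.936) and Lyz1 (0.734). Normal 22-month replicate 2 was low in Dppa3 (0.771) and high in Cldn4 (0.781), Fos (0.855) and Ace (0.848), replicate 1 high in Cdkn1a (0.761) and Dazl (1), and replicate 4 low in Spp1 (0.939). Normal 6-month replicate 1 was high in the matrix score (0.77) and Rhcg (0.821), and replicate 5 low in Junb (0.749). Dwarf 6-month replicate 2 was low in the DNA repair score (0.853), Ninj2 (0.767) and Irs2 (0.817), and replicate 4 low in Nqo1 (0.727) and high in Cldn18 (1). For Dazl and Cldn18 the flagged library had a log2 CPM of -2.08 and -2.27, and the others lay at the floor of -2.87 without counts. Their ratios of 1 thus rest on a few reads. For Il7r, 5830411N06Rik, Sohlh1, Sohlh2, Mafa and, in normal 22-month replicate 2, Dppa3, the flagged library itself lay at that floor.

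Lists whose age response differed between the genotypes by camera's preset correlation had mean log2 differences (dwarf minus normal) of 1.10 for oocyte, 0.79 for granulosa, 0.83 for luteal, 0.41 for cholesterol supply, -1.13 for macrophage, -2.32 for T and NK cell, -3.29 for B and plasma cell, -2.52 for MHC class II, -1.61 for chemokine, -0.28 for proliferation, 0.16 for oxidative phosphorylation, 0.20 for antioxidant, 1.5 for adipocyte, -0.46 for endothelium and -0.86 for immediate-early genes. None of these 15 lists passed with an estimated correlation, where adjusted p ranged from 0.0825 for immediate-early to 0.771 for granulosa genes. Without the 3 libraries in doubt the proliferation list passed in the opposite direction (0.305, camera adjusted p = 0.00407), and the oxidative phosphorylation (-0.125) and antioxidant lists (-0.0719) changed sign and, with the endothelium list (-0.345), no longer passed (camera adjusted p = 0.0568, 0.572 and 0.434). Of 20 fits with a library left out, 12 lost the granulosa call, 11 luteal, 4 cholesterol supply, 3 proliferation, 3 oxidative phosphorylation, 7 antioxidant and 5 endothelium.

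The first pattern weighed is the fall of the oocyte list between 6 and 22 months in dwarf mice. Dilution of ovarian RNA by oviduct or other tissue would lower all ovarian lists alike. The luteal list (0.32) lay 3.12 ± 0.248 (SE over genes, not mice) above the oocyte list (-2.80) in log2 change. That gap cannot decide on dilution, because the luteal score of dwarf mice was already low at 6 months (5.41, against 7.84 in normal mice). Granulosa and theca scores fell with age in dwarf mice (6.50 to 5.83 and 5.75 to 5.04). With the oviduct score as a covariate, the oocyte list averaged -2.03, with 5 genes still lower. Dilution is therefore not excluded. Lower depth at 22 months is argued against, since the oocyte list's mean change was -2.63 ± 0.394 (SD over 24 genes, 22 of them lower) after thinning all libraries to 1365640 counts. A loss of oocytes with age may be the reason, which stays a hypothesis.

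The second is normal 6-month replicate 2. Tissue other than ovary in the sample is a candidate explanation: all 5 ovarian lists compared lay below the other 4 libraries, while the oviduct and smooth muscle lists lay above them. The ovarian and oviduct lists restate the pattern itself, and the ovarian lists share genes, so they give no separate support. Low depth is argued against, since replicates 1 and 3 of the group had fewer counts and luteal scores of 8.89 and 8.52, at least 4.58 above its own (3.95, SD of the other 4 libraries 0.201). An ovary of its own group mixed with other tissue, and a library of another group under a wrong label, cannot be fully told apart. Sult1e1, Hsd17b3 and C7 stood at 0.0731, 0.292 and 1.17 CPM, below every dwarf library (at least 5.67, 5.49 and 21.4 CPM). For these genes that argues against an unmixed dwarf library, but not against a dwarf ovary with little ovarian RNA in the sample. The luteal score of replicate 2 was 1.12 below the lowest of the 15 libraries of the other groups (5.06, SD at most 0.907), but that low score is the pattern itself. Replicate 2 correlated better with normal 22-month libraries (r from 0.874 to 0.938) than with its own group (0.763 to 0.818), and its oviduct score of 8.06 lay within their range (6.25 to 8.85). Its macrophage and mast cell scores (2.91 and 3.71) lay below theirs (4.24 and 4.32 or more).

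The third is the closeness of dwarf 22-month replicates 1 and 4. A single library sequenced or deposited 2 times would differ by counting noise alone, and the chi-square per degree of freedom was 2.51 ± 0.0122 over 13528 genes. RNA of 1 mouse prepared 2 times and 2 similar mice cannot be told apart, because the 0 genes on in one library and off in the other (1 to 43 in the other 9 pairs of the group) are possible under each.

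Among 100 splits, which regrouped the 10 libraries compared (for the interaction, the genotypes within each age), 1 (the real one) called as many genes for age in dwarf mice (1802, highest other 0) and for genotype at 22 months (614, highest other 6). That share of 0.01 is the lowest that 100 splits can give, and it argues against chance there without excluding it. Both comparisons hold dwarf 22-month replicates 1 and 4, which may be RNA of 1 mouse, and the splits took them as separate mice. For age in normal mice 7 splits called as many (1086, highest other 3050) and for genotype at 6 months 6 (735, highest other 1449), so chance cannot be excluded. In each of the 6 and 5 other splits as large, normal 6-month replicate 2 was placed apart from most of its group. For genotype at 6 months, the splits with 805, 1449 and 987 genes also parted dwarf 6-month replicates 3 and 5 from replicates 1, 2 and 4. Oviduct scores were 1.88 and 1.72 in dwarf replicates 3 and 5 and 5.09, 6.40 and 4.83 in dwarf replicates 1, 2 and 4. At 6 months the splits thus point to a structure of the samples that is not normal 6-month replicate 2 alone. For the interaction the real count was 0 (edgeR, with 1127 genes at an unadjusted p under 0.05, DESeq2 17 and limma voom 9; highest other split 1034). Any split calls at least 0, so all 100 had to reach it and the splits say nothing about chance there.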

How the results depend on the processing

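Choices named here were made before the data were examined, except those said to be chosen after seeing the data, and the cause of the changed results was not tested. For age in normal mice (1086 genes), DESeq2 called 1766, limma voom 3859, the fit of only the groups compared 0 (edgeR, with 3748 genes at an unadjusted p under 0.05 in the fit of all groups) and the fit without title numbers 21 to 23 188. Leaving out 1 library gave 481 (normal 22-month replicate 3) to 4384 (normal 6-month replicate 2), with 530 without normal 6-month replicate 4. For age in dwarf mice (1802), DESeq2 called 2747, limma voom 7519, only the groups compared 5169 and a further 2-fold threshold 796. Leaving out 1 dwarf library gave 802 (dwarf 6-month replicate 5) to 1681, with 1014, 972 and 1185 without dwarf 6-month replicates 1, 3 and 4, and 1079, 954, 1127 and 1069 without dwarf 22-month replicates 1 to 4. No normal library was left out alone for this comparison, although leaving out the normal libraries in doubt together gave 4697. For genotype at 6 months (735), DESeq2 called 1414, limma voom 1860, only the groups compared 244 and the 2-fold threshold 435. Leaving out 1 library gave 369 (dwarf 6-month replicate 5) to 1459 (normal 6-month replicate 2), with 380 without dwarf 6-month replicate 1. For genotype at 22 months (614), DESeq2 called 1201, limma voom 2291 and the fit without title numbers 21 to 23 323. Leaving out 1 library gave 262 (dwarf 22-month replicate 4) to 637, with 263, 376 and 321 without dwarf 22-month replicates 1, 3 and 5 and 399 without normal 22-month replicate 1. For the interaction (0 by edgeR, 1127 at an unadjusted p under 0.05), DESeq2 called 17, limma voom 9 and edgeR without normal 6-month replicate 2 called 1. Chosen after seeing the data, the fit without the libraries in doubt called 4848, 4697, 1991, 1762 and 202 genes for the 5 comparisons in this order, the oviduct covariate 1, 642, 1164, 931 and 1, and dwarf 22-month replicates 1 and 4 as 1 library 1107 for age in dwarf mice and 272 for genotype at 22 months. With the replicate number as a block the counts were 1118, 1904, 672, 560 and 0. The main fit did not use the numbers to pair mice, as fixed in advance. Of 30 same-number pairs of libraries (r from -0.215 to 0.719) 10 were above 0.1, and in 10 the same-number library was the closest of the other group. For replicate 2 this held in every pair of groups. Replicate 2 also had the highest oviduct score of each group (8.06 and 8.85 in normal mice at 6 and 22 months, 6.40 and 7.43 in dwarf mice). Structure shared by libraries of that number is therefore not excluded. Of the 34 lists tested, camera called 17, 10, 14, 16 and 15 with the preset correlation, 0, 0, 1, 2 and 0 with an estimated one, and fry 10, 6, 2, 4 and 1. Leaving out 1 library gave 16 to 21, 9 to 12, 9 (without normal 6-month replicate 2) to 14, 12 to 20 and 10 to 19 lists. Among lists that camera called over all libraries, its direction turned in 9 cases. Without the libraries in doubt these were oxidative phosphorylation with age in normal mice (-0.27, then 0.0531), granulosa at 6 months (0.11, then -0.303), proliferation at 6 months (0.24, then -0.0742) and, for the interaction, proliferation (-0.28, then 0.305), oxidative phosphorylation (0.16, then -0.125) and antioxidant genes (0.20, then -0.0719). Without normal 6-month replicate 2 they were proliferation at 6 months (0.0232) and for the interaction (-0.0406), and without normal 6-month replicate 3 oxidative phosphorylation for the interaction (-0.0448). Lists not called over all libraries are outside these 9, and of them the oviduct list at 6 months went from -1.29 to 2.32 (camera adjusted p = 0.0292) and the smooth muscle list with age in normal mice from -0.54 to 0.691 without the libraries in doubt. Left-out fits took proliferation at 6 months up to 0.395 (without normal 6-month replicate 5), the value for the proliferation list, interaction, from -0.407 (the same library) to -0.0317 (without normal 22-month replicate 3), and oxidative phosphorylation for the interaction up to 0.277 (without normal 6-month replicate 5). At an adjusted p under 0.01 the age responses shared 52 genes and the genotype responses 72, against 523 and 254. Over all alternatives, the results of named genes were the same in 5232 cases, gained in 45, lost in 753 and reversed in 0. These cases include panel and interaction genes that were not called, where staying uncalled counts as the same. Most named genes were chosen by a small p or a large change, which makes a reversal unlikely. For the lists that camera called, 980 were the same, 241 lost and 9 reversed. Named calls kept in every fit with a library left out were 24 of 42, 25 of 40, 30 of 39 and 27 of 47 for the 4 pairwise comparisons.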

Other observations

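The tests of Akr1c18 and of the fit without the libraries in doubt were chosen only after the result was seen; the test of carry-over was written before. Several lists passed in none of the 4 pairwise comparisons. For age in normal mice, age in dwarf mice, genotype at 6 months and genotype at 22 months, camera adjusted p was 0.165, 0.662, 0.361 and 0.991 for ovulation genes, 0.906, 0.488, 0.119 and 0.355 for PI3K and FOXO genes, 0.759, 0.109, 0.867 and 0.0577 for hormone receptors, and 0.0569, 0.166, 0.121 and 0.177 for matrix genes. It was 0.793, 0.764, 0.102 and 0.0666 for senescence genes, 0.363, 0.822, 0.61 and 0.991 for skeletal muscle and 0.511, 0.409, 0.995 and 0.81 for neutrophil genes. Growth hormone, IGF and insulin genes had 0.954, 0.637, 0.867 and 0.81, although single genes moved: Irs2, an insulin receptor substrate (its locus overlaps 9530052E02Rik), was higher in dwarf ovaries at 6 months (edgeR adjusted p = 0.00623).

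Oxidative phosphorylation genes shifted slightly as a list, with a mean log2 change of -0.27 with age in normal mice (camera adjusted p = 7.71e-05, or adjusted p = 0.588 with an estimated correlation) and of -0.32 with the dwarf genotype at 6 months (camera adjusted p = 3.27e-06, or adjusted p = 0.703 with an estimated correlation). Neither list call held without the 3 libraries in doubt (camera adjusted p = 0.746 and 0.351) or without normal 6-month replicate 3 alone (0.311 and 0.0899). The list also leaned lower in old dwarf ovaries, with none of 47 genes called (-0.16, camera adjusted p = 0.0314, or adjusted p = 0.874 with an estimated correlation, lost in 4 of 10 fits with a library left out). The DNA repair and theca lists leaned lower with age in normal mice, with 1 of 25 and 1 of 12 genes past the threshold (camera adjusted p = 0.00653 and 0.0392, or adjusted p = 0.504 and 0.521 with an estimated correlation). The DNA repair call was lost without normal 6-month replicate 5 (camera adjusted p = 0.115) and the theca call in 6 of 10 fits with a library left out (up to 0.128). In old dwarf ovaries the endothelial list leaned lower, with none of 11 past the threshold (camera adjusted p = 0.00967, or adjusted p = 0.748 with an estimated correlation, and by camera 0.146 and 0.0746 without normal 22-month replicates 1 and 4).

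In the fit without the libraries in doubt, edgeR called 202 genes for the interaction. They included Phyhip (log2 1.60 ± 0.263, edgeR adjusted p = 0.0231), the lipid elongase gene Elovl6 (1.88 ± 0.315, edgeR adjusted p = 0.0258), Ctgf (-1.58 ± 0.310, edgeR adjusted p = 0.0394), the mast cell chymase gene Cma1 (-2.79 ± 0.587, edgeR adjusted p = 0.0395), the fat droplet gene Plin1 (2.13 ± 0.459, edgeR adjusted p = 0.0432) and the oocyte gene Nlrp5 (2.29 ± 0.528, edgeR adjusted p = 0.0483). Of 80 tested ribosomal protein genes 29 were lower and 0 higher in that fit (mean log2 difference -0.56 ± 0.496, SD over genes); many have pseudogenes, so the assignment of their reads is uncertain. These genes were picked from the same values that called them and remain hypotheses.

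Akr1c18 is repressed by prolactin, which dwarf mice lack, so luteal cells that were present but without prolactin would show more of it. Its log2 difference at 6 months differed from the mean of the other 10 luteal genes (-2.70, SD 2.12) by -4.6. Kept luteal cells without prolactin and fewer luteal cells cannot be told apart by this, since the gene was picked for its fall and the gap is less than 2 times its spread of 2.49.

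Normal 6-month replicate 3 held some transcripts of genes that were high in dwarf ovaries. RNA or reads of dwarf libraries carried into it, and true expression in that mouse, cannot be told apart: over 8 such genes its excess had a median of 13.6% of the dwarf level (quartiles 1.56 and 19.8%), 62.5% of them were above replicates 1, 4 and 5, and the genes had only 286 counts there. The same measure in replicates 1, 4 and 5 was -0.797, 1.23 and 0.0372%. Such carry-over would shrink, not widen, the genotype differences at 6 months.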
